A study of Homo sapiens with 6 samples.

How the data were processed

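RNA from HK-2 cells treated with cisplatin was made into libraries with a stranded mRNA kit from 2 µg of total RNA, per the labels' protocols. The submitters' processing notes name Trimmomatic 0.36, a read trimmer, and the GRCh38 genome build; the aligner, the counter and the annotation release are not given in the sources used here. The deposited table holds 18969 Ensembl genes with GRCh38.p13 positions, of which 13678 are protein coding and 3576 are lncRNA genes; 2759 rows carry no symbol and were named by identifier. No row had fewer than 10 counts summed over the 6 libraries, so the table had been filtered on low counts before deposit.

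The authors deposited raw read counts per gene and library, which are whole numbers with different totals. The authors also deposited FPKM values, and the ratio of count to FPKM was constant between libraries to a relative spread of 6.9e-14, so they rest on the same counts, with a fixed length per gene. The FPKM of a library sum to more in the libraries labelled overexpression (605615 to 626091) than in controls (484862 to 519524). The authors' deposited log2 fold changes, p-values and adjusted p-values have no stated test; adjusted p fits the Benjamini-Hochberg method over 14923 rows, with the value 1 filled in for 4046 rows of low counts. Their table has 3834 genes with an adjusted p under 0.05, 1760 up and 2074 down, and a DESeq2 run on the deposited counts gave the same numbers. The authors' values were used only where their table is named.

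Samples were grouped by the library names in the labels, and all 6 columns of counts matched a sample. The depth was 16865460 to 23458333 counts per library, and no libraries were identical. The analysis of the 15046 genes kept by filterByExpr used edgeR 4.0.16 in R 4.3.3 with TMM scaling, glmQLFit and glmQLFTest, on the group alone, with Benjamini-Hochberg adjustment at 0.05. Standard errors are the absolute log2 fold change divided by the square root of F. Log2 values used a prior count of 2. The biological coefficient of variation was 0.249. For NFE2L1, ACSL4 and NRF1 an exact two-sided permutation test over the 20 assignments of the libraries was added.

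For 43 gene lists fixed before the data were examined, members up and down were counted at the adjusted p over all genes and adjusted over the list alone. The 39 lists with at least 5 tested members were tested with camera at a preset correlation of 0.01, adjusted over the 39 lists, and again with an estimated correlation and with fry. With the preset correlation 8 lists passed, and with the estimated correlation 0 passed, against 9 with fry, which tests only whether members move on balance one way. Named genes were NFE2L1, NRF1 and ACSL4; the 12 largest rises and 12 largest falls among protein-coding genes with an official symbol, an adjusted p under 0.05, a mean FPKM of at least 2 in the higher group and no overlap between groups; and the 4 members with the smallest adjusted p of each list described. Genes outside this rule are marked as named after their values were seen. Of the genes that this rule takes from the lists, 1 is left out of the text.

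Alternatives set before the data were examined were no filter, a filter of FPKM of at least 5 in at least 3 libraries, DESeq2 size factors, the DESeq2 1.42.0 Wald test, limma 3.58.1 on log2(FPKM + 1) over genes with FPKM of at least 1 in at least 3 libraries, pseudocounts of 0.5 and 0.1, no variance trend, rescaling of FPKM to a common sum, quantile normalization, a replicate block, and leaving out each library. The length and GC offset was added after the data were seen. It is a smooth of each library's log2 deviation on gene length, taken from the ratio of counts to FPKM, and on GC content, fitted with mgcv 1.9.3, and a version with length alone was run too. GC content came from the longest GENCODE 29 transcript, which matched 98.45% of rows. Coordinates are those of the deposited table.

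The fit was tested on simulated counts for the 15046 genes, drawn from the libraries' means, sizes and spread, with 200 genes changed. It recovered 4.41% of genes changed 1.5-fold, 30.3% of those changed 2-fold and 93.9% of those changed 4-fold, with 9 false calls. With a length and GC trend like the observed added, there were 267 false calls, and 0 after the offset. The added trend had the form that the offset fits and removes, so the 0 does not show how the offset acts on other bias. The simulated spread came from the fit without the offset, which already holds length and GC deviations within groups. The 267 therefore cannot be set against the number of calls in the real data. In simulations of 39 lists, a proteasome list raised 2-fold was called. With no list changed 1 list was called, with the length and GC trend added 2 were, and 0 after the offset. The draws carried no correlation between members of a list, which was estimated at up to 0.82 in the real data. These list counts therefore cannot show how often the list test calls unchanged lists in the real libraries. Splits of the real libraries that mix the groups called 6 to 11 lists. Going by the recovery of changed genes, most changes of 2-fold or less are missed at this depth and number of libraries. Counts of near-identical genes and pseudogenes depend on how the authors treated shared reads, which was not analysed here. Figures were drawn with matplotlib 3.10.9.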

Results

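Messenger RNA was measured by sequencing in HK-2 cells, an immortalised line of human kidney proximal tubule epithelium. All cultures received cisplatin at 20 µM, a platinum drug that crosslinks DNA and injures the tubule. The 6 libraries formed 2 groups, with 3 control libraries of wild-type cells and 3 libraries labelled as NFE2L1 overexpression. NFE2L1 encodes a transcription factor, often called Nrf1, that switches on proteasome genes. It is not NRF1, the nuclear respiratory factor. The control libraries held 22365895, 21929840 and 19821519 counted reads, and the libraries labelled overexpression held 16865460, 23458333 and 21582267. The design asks whether NFE2L1 alters transcripts of cell death, and of ferroptosis in particular, in cells exposed to cisplatin. Ferroptosis is an iron-dependent form of cell death driven by peroxidation of membrane lipids. ACSL4, an enzyme that loads polyunsaturated fatty acids into those membranes, was of special interest. No label said whether the libraries came from separate cultures, so the p-values measure the spread between these libraries, which may be technical.

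NFE2L1 (ENSG00000082641, chromosome 17, 48048329 to 48061545, plus strand, GRCh38.p13) was raised in only part of the group labelled for it. Library 1 labelled overexpression stood at 244.7 CPM (counts scaled to library size with TMM factors), inside the control range of 234.2 to 253.4 CPM. Library 2 stood at 744.0 CPM and library 3 at 339.5 CPM. The group means were 244.6 ± 9.68 CPM in controls and 442.8 ± 265.2 CPM in the libraries labelled overexpression (SD, n = 3 each). The log2 fold change was 0.86 with a standard error of 0.35, which did not pass (adjusted p = 0.115, edgeR quasi-likelihood test). An exact two-sided permutation test of the 6 log2 values gave p = 0.3, where 0.1 is the smallest value that 3 libraries against 3 can give. Without library 1 labelled overexpression the log2 fold change was 1.14 and passed (edgeR adjusted p = 0.0286), and without library 2 it was 0.25 (adjusted p = 0.265). The authors' deposited table lists a log2 fold change of 0.82 for NFE2L1 with an adjusted p of 0.0761. NRF1 had a log2 fold change of -0.17 (edgeR adjusted p = 0.616). Every direction given from here on compares the libraries labelled overexpression with controls, and includes library 1, in which NFE2L1 was not above the controls.

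ACSL4 (ENSG00000068366, chromosome X, 109624244 to 109733403, minus strand) fell in the libraries labelled overexpression. Controls held 335.8, 402.3 and 266.3 CPM, against 210.5, 106.5 and 182.7 CPM in the libraries labelled overexpression, so every one of these lay below every control. The means were 334.8 ± 68.0 and 166.6 ± 53.8 CPM (SD, n = 3 each), a log2 fold change of -1.01 with a standard error of 0.26 (edgeR adjusted p = 0.0304). The exact two-sided permutation test gave p = 0.1, its smallest possible value. The authors' deposited table lists -1.04 with an adjusted p of 0.00381. The call did not hold without control 1 (adjusted p = 0.114), control 2 (0.121) or library 3 labelled overexpression (0.0718). With an offset for gene length and GC content, chosen after the data were seen, the log2 fold change was -0.42 with a standard error of 0.18 (edgeR adjusted p = 0.239).

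**Figure D1:**
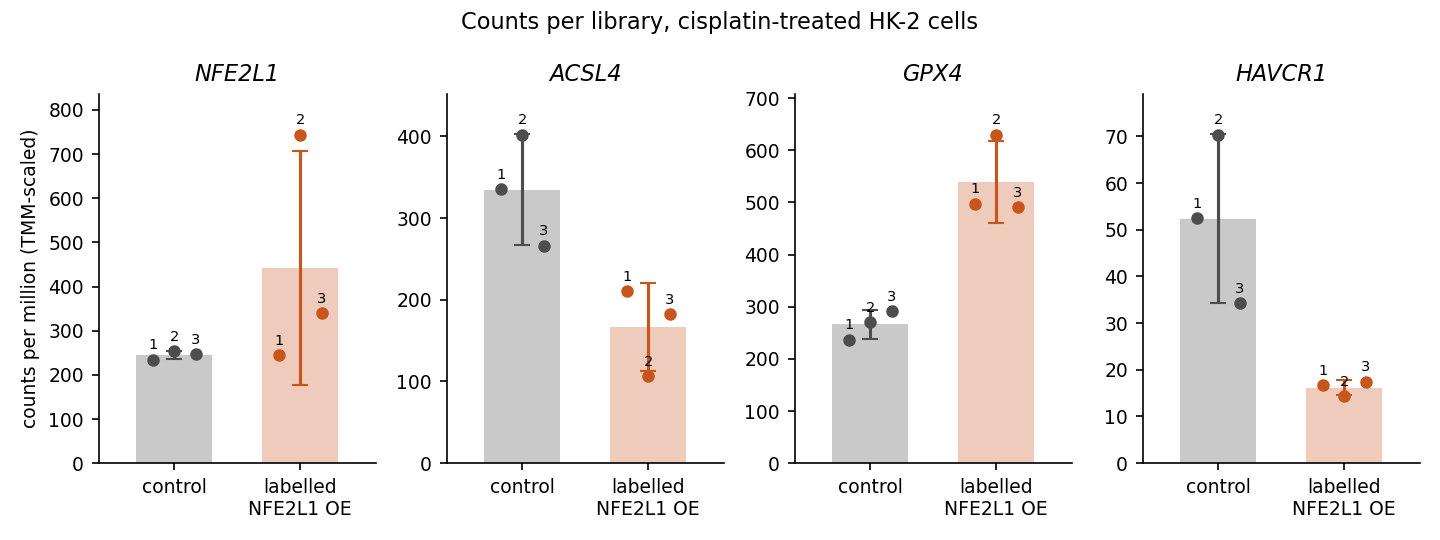
TMM-scaled CPM (vertical axes from 0) of 4 genes in 3 control libraries (grey) and 3 libraries labelled NFE2L1 overexpression (orange). Numbered points are libraries, bars are means and whiskers are SD. NFE2L1 in library 1 labelled overexpression (244.7 CPM) lies within the control range of 234.2 to 253.4 CPM, while ACSL4, GPX4 and HAVCR1 do not overlap between the groups.

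Across all genes the groups differed broadly. Of 15046 genes tested, 1448 rose and 1428 fell in the libraries labelled overexpression (edgeR, Benjamini-Hochberg adjusted p under 0.05), and 594 of the risen and 541 of the fallen genes passed 2-fold. The groups did not overlap in 6413 genes, or 42.6%, where chance gives 10%. AKR1B10, an aldo-keto reductase that detoxifies aldehydes, rose from 0.798 ± 0.199 to 4.19 ± 2.13 CPM (SD, n = 3 each, log2 fold change 2.38, SE 0.43, edgeR adjusted p = 0.0128). Among the other large rises were TMEM37 at 2.30, the metal-binding MT1A at 2.26, the myelin and lymphocyte protein gene MAL at 2.04, the sulfotransferase gene SULT1A1 at 1.87 and EGFL7 at 1.85 on the log2 scale. TSSK3, a testis kinase gene, had the largest rise under the rule for named genes, 2.69 on the log2 scale, from 0.405 ± 0.239 CPM in controls (SD, n = 3). H2AW, WDR38, TESC, JOSD2 and CCDC85B completed the 12 largest rises, with log2 fold changes of 1.91, 1.81, 1.80, 1.78 and 1.77.

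Under the rule for named genes, NFAT5, the transcription factor of the response to osmotic stress, fell most. It went from 37.0 ± 8.95 to 7.07 ± 1.35 CPM (SD, n = 3 each, log2 fold change -2.39, SE 0.25, edgeR adjusted p = 0.0105). The interstitial collagenase gene MMP1 fell from 106.2 ± 55.4 to 24.5 ± 3.17 CPM (log2 fold change -2.12, edgeR adjusted p = 0.0141). HAVCR1, which encodes the tubular injury marker KIM-1, fell from 52.4 ± 18.1 to 16.2 ± 1.61 CPM (log2 fold change -1.70, SE 0.27, edgeR adjusted p = 0.0109). The integrin gene ITGA1 (-1.77), the interleukin-1 receptor subunit gene IL1RAP (-1.63), ZDBF2 (-1.69), TXNDC16 (-1.62) and the histone deubiquitinase gene MYSM1 (-1.60) fell too. PCDHGC3 (-2.07), GTF2I (-1.81), NOMO3 (-1.74) and NOMO2 (-1.58) share exons or near-identical copies with other loci, so their counts are uncertain, as are those of SULT1A1 and the metallothioneins. Without control 1 the only gene that passed was MMP1 (log2 fold change -2.50, edgeR adjusted p = 0.0405), and without control 2 none did, at 3962 and 3863 genes with an unadjusted p under 0.05. No member of the gene lists described below therefore passed singly without either of these controls. Without library 1 labelled overexpression, 2586 genes passed, and without control 3 or library 3 labelled overexpression 1373 and 1555 did.

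Fold changes followed transcript size and base composition. Short and GC-rich genes had higher counts in the libraries labelled overexpression, and long, AT-rich genes had lower counts. Across genes, which are not independent replicates, the log2 fold change had a Spearman rho of -0.54 with gene length and 0.55 with GC content. In 10 bins of gene length, the median was 0.61 in the shortest bin, of median length 0.594 kb, and -0.49 in the longest, of median length 8.99 kb. In that longest bin, libraries 1, 2 and 3 labelled overexpression deviated from the mean of the 6 libraries by 0.018, -0.66 and -0.16. Controls deviated by 0.33, 0.43 and 0.069, so library 1 was not below that mean and lay close to control 3. With an offset for length and GC content in each library, 248 genes passed (166 up, 82 down), of which 199 were among the 2876 above, and 121 passed 2-fold. Of the genes named so far, AKR1B10, TMEM37, SULT1A1, EGFL7, NFAT5, MMP1, GTF2I, ITGA1, HAVCR1 and IL1RAP still passed. On FPKM rescaled to the same sum in every library, the median of all genes moved to -0.38 and 522 genes rose against 4129 that fell. On log2(FPKM + 1) without rescaling, 1198 rose and 2027 fell (limma).

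**Figure D2:**
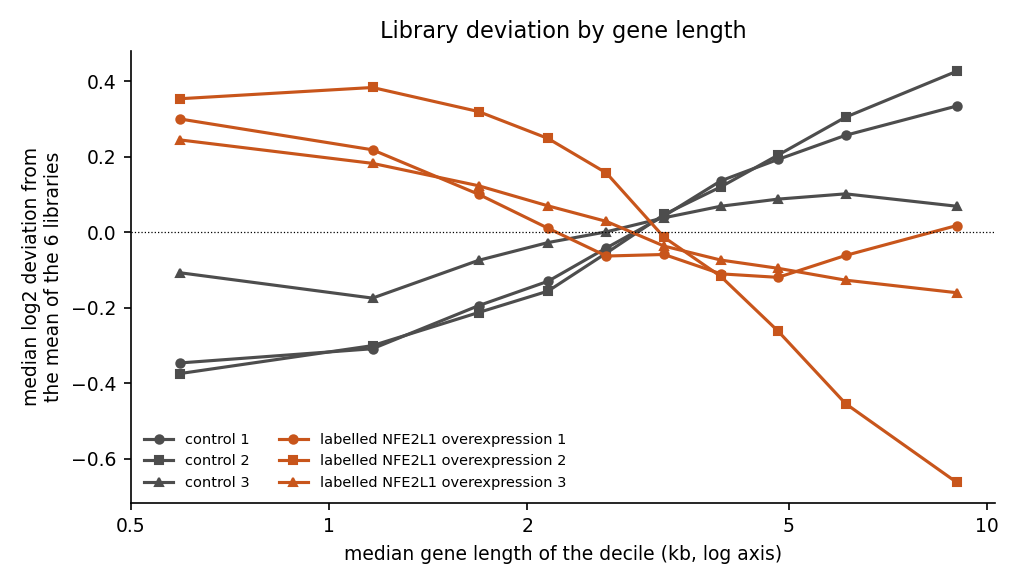
Median log2 deviation of each library from the mean of the 6 libraries (vertical axis) in 10 bins of gene length, placed at the median length of each bin (kb, log axis). Controls (grey) lie below 0 for the shortest genes, at -0.35, -0.37 and -0.11, and the libraries labelled NFE2L1 overexpression (orange) lie above it, at 0.30, 0.35 and 0.24. For the longest genes controls lie at 0.33, 0.43 and 0.069, and the libraries labelled overexpression at 0.018, -0.66 and -0.16.

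Some genes of ferroptosis changed, and most did not pass. Among 33 drivers tested, 7 fell and 3 rose (6 up and 10 down adjusted over the list alone). TFRC, the transferrin receptor that imports iron, fell from 1070 to 544 CPM (log2 fold change -0.98, edgeR adjusted p = 0.0126). ELOVL5, an elongase of polyunsaturated fatty acids, fell by 0.80 on the log2 scale and the zinc and iron importer gene SLC39A14 fell by 0.70. The driver PEBP1, a partner of 15-lipoxygenase, rose by 0.77. The other drivers that passed, named after their values were seen, were PHKG2 and CHAC1 upward and IREB2, DPP4, ACSL4 and NCOA4 downward. Among 36 suppressors, 8 rose and 1 fell (9 up and 2 down adjusted over the list alone). GPX4, the peroxidase that reduces lipid hydroperoxides, rose from 266.2 ± 27.4 to 539.6 ± 78.6 CPM (SD, n = 3 each, log2 fold change 1.02, SE 0.16, edgeR adjusted p = 0.0109). HSPB1 rose by 1.29, the ferritin heavy chain gene FTH1 by 0.91 and the thioredoxin gene TXN by 0.81, while the thioredoxin reductase gene TXNRD1, named after its value was seen, was the suppressor that fell. FTH1 has many processed pseudogenes, so its counts are uncertain. The pathway as drawn in common maps had 5 genes up and 6 down of 34 (6 and 7 adjusted over the list alone), with the ferritin light chain gene FTL among those up, at 0.99.

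As whole lists none of these passed. The median log2 fold change was -0.0080 for drivers (camera adjusted p = 0.574), 0.28 for suppressors (0.0802) and 0.0038 for the common pathway (0.959). The suppressor list passed without control 2 and without library 2 labelled overexpression (camera adjusted p = 0.0498 and 0.0171 at the preset correlation). With all libraries and an estimated correlation its camera adjusted p was 0.733. The suppressor median was 0.14 without control 1. When single libraries were left out, the other medians ran from -0.059 to 0.086 for drivers and from -0.069 to 0.098 for the common pathway, so their signs are not settled. With the length and GC offset, 0 drivers and 0 genes of the common pathway passed singly (edgeR, against 2975 genes of all kinds with an unadjusted p under 0.05), and 2 suppressors did, CISD1 and CISD2, named after their values were seen. GPX4 then had a log2 fold change of 0.13 (edgeR adjusted p = 0.637). The suppressor list passed with a median of 0.27 (camera adjusted p = 0.00425, and 0.738 with an estimated correlation). Without the offset, its median stood above the control mean by 0.33, 0.12 and 0.17 in libraries 1, 2 and 3 labelled overexpression. Relative to genes matched on length, GC content and level, the groups overlapped for this list. Its median without the offset lay at percentile 98.8 of 10000 lists matched on these properties, which do not carry the correlation between members. The suppressor median was -0.16 on FPKM rescaled to a common sum, above the -0.38 of all genes on that scale.

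Transcripts of apoptosis also went both ways. Of 28 genes that promote it, 6 rose and 2 fell (7 and 2 adjusted over the list alone). The BCL-2 family killers BOK, BAD and BAX rose by 1.06, 1.14 and 0.86 on the log2 scale, and APAF1, the scaffold of the apoptosome, fell by 1.14 (edgeR adjusted p from 0.0109 to 0.0185). Of 15 genes that restrain apoptosis, 3 fell and 0 rose, the same adjusted over the list alone. They were BIRC2 (-1.01), MCL1 (-0.63) and TNFAIP3 (-1.15). In the list of necroptosis and pyroptosis, PYCARD (1.52), the pore former GSDMD (0.96) and NINJ1 (0.72) rose, CYLD (-0.71) fell, and 8 of 12 did not pass, with the same counts adjusted over the list alone. None of the 3 lists passed as a whole (camera adjusted p = 0.664, 0.540 and 0.832), and with the length and GC offset 0 of their members passed singly.

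Many proteasome subunit genes, the best known targets of NFE2L1, rose. Of 34 tested, 19 rose and 0 fell (22 up and 1 down adjusted over the list alone), with a median log2 fold change of 0.65 (camera adjusted p = 2.04e-08). The call was lost with a correlation estimated per list (adjusted p = 0.559 with an estimated correlation). PSMB3 rose from 169.8 ± 18.6 to 450.1 ± 86.5 CPM (SD, n = 3 each, log2 fold change 1.41, SE 0.18, edgeR adjusted p = 0.0105), PSMA7 by 1.23, PSMB6 by 1.22 and PSMB7 by 0.98. The list median stood above the control mean by 0.42, 0.79 and 0.46 in libraries 1, 2 and 3 labelled overexpression, so it was raised in library 1 as well, where NFE2L1 was not. These genes are short, at a median of 1.48 kb, and with the length and GC offset 6 rose and the median was 0.41 (camera adjusted p = 1.04e-11). No list passed with the offset and an estimated correlation, where the smallest adjusted p was 0.738. Among genes of endoplasmic reticulum-associated degradation, which supplies the proteasome, EDEM3 (-1.42), EDEM1 (-0.63) and UBQLN1 (-0.51) fell, UFD1 (0.66) rose, and 20 of 26 did not pass, the same adjusted over the list alone. With the offset only DERL2 of that list, named after its value was seen, passed, upward. Of 16 relatives and partners of NFE2L1 only NFE2L3 passed, at -0.72, and 0 passed adjusted over the list alone or with the offset.

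Some genes that bind metals or buffer oxidants rose as well. All 6 metallothionein genes rose, over all genes and adjusted over the list alone, with a median of 1.23 (camera adjusted p = 3.94e-07; adjusted p = 0.559 with an estimated correlation). MT2A rose from 396.4 to 1268 CPM, a log2 fold change of 1.68. Of 31 targets of the antioxidant response element, 11 rose and 1, TXNRD1, fell (13 and 3 adjusted over the list alone), with a median of 0.51 (camera adjusted p = 0.000284; adjusted p = 0.733 with an estimated correlation). The glutathione transferase gene GSTP1 rose by 1.27, TALDO1 of the pentose phosphate pathway by 1.09 and the aldose reductase gene AKR1B1 by 0.92. In the glutathione system 6 of 25 genes rose and 0 fell (7 and 1 adjusted over the list alone), among them GSTO1 (0.80) and GPX1 (1.04), with a median of 0.32 (camera adjusted p = 0.0121; adjusted p = 0.733 with an estimated correlation). That median was -0.091 on FPKM rescaled to a common sum, where all genes stood at -0.38. Without control 1 the glutathione list did not pass (camera adjusted p = 0.0658). With the length and GC offset the medians were 0.57 for metallothioneins, 0.32 for antioxidant targets and 0.19 for the glutathione system, at camera adjusted p of 0.00412, 0.00412 and 0.125, and 0, 1 and 0 members passed singly. The medians without the offset lay at percentiles 98.1, 95.5 and 47.7 of 10000 lists matched on length, GC content and level. Relative to matched genes, the groups overlapped for metallothioneins and for antioxidant targets. The antioxidant median was 0.27 without library 2 labelled overexpression, and the list still passed (camera adjusted p = 0.000663).

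Many genes of the translation and respiration machinery rose. Of 74 cytosolic ribosomal protein genes, 68 rose and 0 fell (71 up adjusted over the list alone), with a median of 0.92 (camera adjusted p = 8.69e-47). RPL28, RPS21 and RPS15 rose by 1.24, 1.32 and 1.28 on the log2 scale. Of 40 nuclear genes for oxidative phosphorylation, 27 rose and 0 fell (31 up adjusted over the list alone), with a median of 0.76 (camera adjusted p = 1.58e-14). COX5B, COX6B1, ATP5MC1 and ATP5F1D rose by 1.30, 1.21, 1.07 and 1.48. Both calls were lost with a correlation estimated per list (adjusted p = 0.559 with an estimated correlation in each). Members of these lists are among the shortest genes, at medians of 0.878 and 1.14 kb, and ribosomal protein genes have many processed pseudogenes, so single counts are uncertain. With the length and GC offset 18 ribosomal and 8 respiratory genes rose, at medians of 0.57 and 0.54 (camera adjusted p = 2.89e-36 and 5.67e-15). Of 13 genes encoded in the mitochondrion, MT-ND3 rose by 1.01 and MT-ND4L fell by 1.13 (0 up and 1 down adjusted over the list alone), and the list had a camera adjusted p of 0.959. Its median of 0.13 lay at percentile 0 of 10000 lists matched on length, GC content and level, whose median was 0.71. Those matched lists do not carry the correlation between members. MT-ND4L still passed with the offset and MT-ND3 did not.

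Some genes of mitosis fell. Of 27 genes of the G2 and M phases, 12 fell and 2 rose (15 and 2 adjusted over the list alone), with a median of -0.45 (camera adjusted p = 0.000178; adjusted p = 0.559 with an estimated correlation). ANLN, which organises the cleavage furrow, fell from 380.1 to 127.1 CPM (log2 fold change -1.58, SE 0.18, edgeR adjusted p = 0.0105), the checkpoint genes BUB1B and BUB1 fell by 1.34 and 0.76, and ECT2 fell by 1.14. The risen members, named after their values were seen, were CDC20 and AURKB. With the length and GC offset ANLN and BUB1B still passed, at a list median of -0.25 (camera adjusted p = 0.000106). Genes of S phase went both ways, with CDT1 (0.93), GINS2 (0.87) and TK1 (0.81) up, CCNE2 (-1.06) down and 21 of 27 not passed, the same adjusted over the list alone, and only GINS2 passed with the offset. None of 12 replication histone genes passed (edgeR, with 5391 of all genes at an unadjusted p under 0.05). Among fits that left out 1 library, they passed as a list only without control 3 (camera adjusted p = 0.000658, against 0.180 with all libraries). With all libraries the estimated correlation of this list was 0.76, and its camera adjusted p with it was 0.971.

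Genes that repair the crosslinks made by cisplatin mostly fell where they changed. Of 32, 9 fell and 1 rose (9 and 2 adjusted over the list alone), with a median of -0.32 (camera adjusted p = 0.0462; adjusted p = 0.559 with an estimated correlation). BRCA2 fell by 1.26, XRCC2 by 0.84 and FANCM by 1.13, while the nuclease subunit gene ERCC1 rose by 0.89. The list did not pass without control 2 (camera adjusted p = 0.0533) or with the length and GC offset (0.470), where 0 members fell and only ERCC1 passed, upward (edgeR adjusted p = 0.0496). Its median lay at percentile 39.15 of the lists matched on length, GC content and level. In the fixed list for cisplatin transport, whose members need not all carry cisplatin, ABCB1 (-0.78), ABCC5 (-0.72) and LRRC8D (-0.79) fell. The other 12 of 15 did not pass, the same adjusted over the list alone (camera adjusted p = 0.106). Of 30 targets of p53, PHLDA3 (1.09) and BAX rose, RRM2B (-0.99) and TP53INP1 (-1.05) were among 4 that fell, the same adjusted over the list alone, and the list had a camera adjusted p of 0.959. No transporter or p53 target passed singly with the offset (edgeR, with 2975 genes of all kinds at an unadjusted p under 0.05).

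Markers of tubular injury and of matrix did not pass as lists in the main fit. Of 22 injury and repair genes, HAVCR1 fell and S100A6 (1.09), KRT18 (0.62) and TIMP1 (0.80) were among 4 that rose (6 up and 1 down adjusted over the list alone). The list had a camera adjusted p of 0.174, and of 0.0227 without library 2 labelled overexpression. With all libraries and an estimated correlation it was 0.694. With the length and GC offset HAVCR1 had a log2 fold change of -1.88 (SE 0.27, edgeR adjusted p = 0.0337) and no other member passed. Of 25 genes of matrix and mesenchymal transition, 7 fell and 0 rose (8 down adjusted over the list alone; camera adjusted p = 0.0802). The fibronectin gene FN1 fell from 6290 to 2889 CPM (log2 fold change -1.12, edgeR adjusted p = 0.0105), TGFB2 fell by 1.58, THBS1 by 1.24 and ZEB2 by 0.96. This list passed with the length and GC offset (median -0.19, camera adjusted p = 0.0459; adjusted p = 0.738 with an estimated correlation). Without the offset it passed in 3 of 6 fits that each left out 1 library, at camera adjusted p from 0.00762 to 0.256. In lipid and polyunsaturated fatty acid metabolism 8 of 40 fell and 0 rose, the same adjusted over the list alone, including ACSL5 (-0.81), ACADM (-0.70) and FAR1 (-0.94) beside ELOVL5 and ACSL4 (camera adjusted p = 0.106). That list passed without control 1 and without library 1 labelled overexpression (camera adjusted p = 0.0485 and 0.04997 at the preset correlation). With all libraries and an estimated correlation its camera adjusted p was 0.808. Its median of -0.11 was 0.047 without control 2. Iron handling had 4 genes up, among them the ferritin genes FTH1 and FTL, and 5 down, among them TFRC and SLC39A8 (-0.64), of 23 tested (5 and 5 adjusted over the list alone; camera adjusted p = 0.959). With that offset TGFB2 was the only matrix gene to pass singly, 0 genes of lipid metabolism passed, and the iron list had CISD1 and CISD2 up and 0 down (edgeR).

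**Figure D3:**
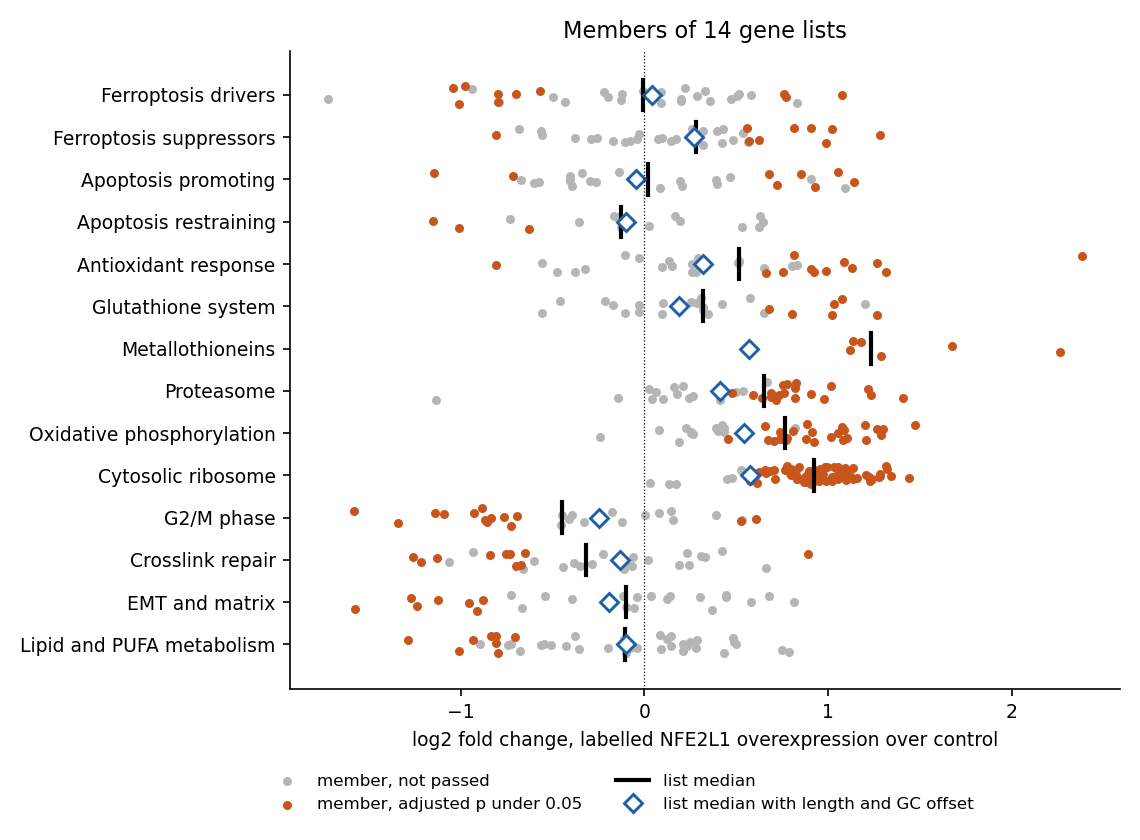
Log2 fold change of the libraries labelled NFE2L1 overexpression over controls (horizontal axis) for the members of 14 gene lists (vertical axis). Points are genes, orange where the adjusted p was under 0.05; black bars are list medians and blue diamonds are medians with the length and GC offset. The medians of the ribosomal, respiratory and proteasome lists, at 0.92, 0.76 and 0.65, move to 0.57, 0.54 and 0.41 with the offset.

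Stress and inflammatory programmes showed scattered changes. In the integrated stress response TRIB3 (1.19), DDIT4 (0.69), PCK2 (0.68) and SHMT2 (0.55) were among 5 of 30 genes that rose, with 0 down, and none passed adjusted over the list alone (camera adjusted p = 0.185). In the unfolded protein response SDF2L1 (1.41) and SEC61B (0.83) rose, and CANX (-0.82) and the kinase gene EIF2AK3 (-1.20) were among 3 that fell, of 22 (4 and 5 adjusted over the list alone). NF-kB targets had NFKBIA (0.62) and CCL2 (1.10) up and TNFAIP3 and NFKBIZ (-0.73) down, of 27, the same adjusted over the list alone. Interferon-stimulated genes had 3 up, among them BST2 (0.77) and IFI35 (0.86), and 4 down, among them SAMD9 (-1.24) and SAMD9L (-1.20), of 30, and likewise adjusted over the list alone. Cholesterol synthesis had EBP (1.03), PMVK (1.14), MVD (1.20) and FDPS (0.70) up and 2 of 24 genes down (5 and 2 adjusted over the list alone). None of these 5 lists passed as a whole (camera adjusted p from 0.185 to 0.832). EIF2AK3 was their only member that passed with the length and GC offset (edgeR adjusted p = 0.0494).

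The other lists also held few changes. Among heat shock genes HSPB1 and HSPE1 (0.99) rose and HSPA4L (-0.97) and DNAJB4 (-1.11) fell, of 20. GAPDH (0.99) and GPI (0.65) rose among 28 genes of glycolysis and hypoxia, and 0 fell. CTSD, a lysosomal protease gene, rose by 1.39 and LAMP2 fell by 0.66 among 29 genes of autophagy and the lysosome. Of 30 immediate early and MAPK target genes, JUND (1.01) rose and EREG (-1.02) fell. Counts for these 4 lists were the same adjusted over the list alone. The junction genes CLDN4 and DSP changed by 1.39 and -1.21, of 12 (2 up and 1 down adjusted over the list alone). SMPDL3A (-0.81) fell among 8 genes of cholesterol efflux (1 and 1 adjusted over the list alone), and 0 of 8 genes of proximal tubule function passed over all genes (2 up adjusted over the list alone). The camera adjusted p of these 7 lists ran from 0.543 to 0.959, and only GPI and DSP passed singly with the length and GC offset (edgeR).

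Of markers of other cell types, 7 of fibroblasts and pericytes, 5 of podocytes, 3 of the distal nephron, 2 of endothelium and 2 of leukocytes could be tested. LUM, a fibroblast proteoglycan gene, fell from 39.7 to 14.9 CPM (log2 fold change -1.42, edgeR adjusted p = 0.0105), and no other marker passed; LUM still did with the length and GC offset. The nuclear transcript MALAT1 had 454.2 CPM in controls and 1022 CPM in the libraries labelled overexpression (log2 fold change 1.17, edgeR adjusted p = 0.0595). The 3 libraries labelled overexpression held 1502, 411.6 and 1153 CPM of it, so library 2 lay below every control. MALAT1 rose with the length and GC offset (edgeR adjusted p = 0.0451). Mitochondrial genes took 5.76, 3.55 and 6.11% of counts in controls and 5.69, 3.93 and 6.43% in the libraries labelled overexpression. The signal recognition particle RNA gene RN7SL1 had a log2 fold change of 1.66 (edgeR adjusted p = 0.0521). In principal components of the log2 values, library 2 labelled overexpression stood apart from the rest on the first component, which held 51.8% of the variance. Library 1 labelled overexpression stood apart on the second, at -58.7 where the next lowest was -15.4, and that component held 29.1%.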

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

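The length and GC offset and the length offset were chosen after the data were seen; all other alternatives were set before the data were examined. The count of 2876 genes stayed within 1.5 times under other filters, DESeq2, size factors and 5 limma settings, but was 4651 on FPKM rescaled to a common sum, since that sum is larger in the libraries labelled overexpression. It was 248 with the length and GC offset and 1017 with the length offset. Leaving out each library gave 0 to 3649 genes, with 1 without control 1 and 0 without control 2 (edgeR; 3863 at an unadjusted p under 0.05 without control 2). These fits have fewer samples. The 1135 genes past 2-fold became 686 with the strict filter, where fewer genes were tested. They became 581, 579 and 486 with limma on log2(FPKM + 1), without a trend and with quantile normalization, where the pseudocount shrinks low genes. They were 1759 on rescaled FPKM, 121 with the length and GC offset and 385 with the length offset, and 0 to 1296 when leaving out each library.

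With the replicate block 0 genes passed, and 0 past 2-fold (edgeR; 4413 genes at an unadjusted p under 0.05, and DESeq2 without the block called 3834). Deviations of libraries with the same number correlated at 0.0061, -0.51 and 0.088 across genes, so they gave no sign of pairing by number. Control 2 correlated best with library 1 labelled overexpression, at 0.60. Deviations from a group mean of 3 libraries constrain one another, so these values cannot exclude that equal numbers mark a shared culture or day.

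NFE2L1 kept its direction and did not pass in any setting except without library 1 labelled overexpression, at 1.14, and ranged from 0.25 to 1.14 when leaving out each library. ACSL4 stayed lower in every setting. It did not pass with the replicate block (-1.04), the length and GC offset (-0.42) or the length offset (-0.71), and ranged from -1.21 to -0.77 when leaving out each library. Its adjusted p over all alternatives ran from 0.00381 to 0.239. Of 39 lists, 8 passed; 0 did with camera at an estimated correlation (9 with fry), while 6 to 11 did in the other settings. NOL3, an apoptosis repressor gene whose log2 fold change of 0.62 did not pass, had -0.19 with the length and GC offset; the cause was not tested for these changes beyond the fewer samples or genes named. Among the other comparisons of a gene, a list median or a count of list members with a setting, 1394 kept direction and side of the threshold or a count within 1.5 times, 350 lost the call, 160 counts of members moved further and 1, NOL3, reversed. Depth was similar between the libraries, and genes under 1 CPM in controls, such as TSSK3 and MT1A, rest on few counts.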

Other observations

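The matched-list tests of ACSL4, the proteasome and the ribosome and the splits of the list tests were set before their results were seen, though the values with the offset were already known; the other tests here were chosen after the results were seen. The gene families below were also picked after the data were seen, from symbols, and tested with camera over 9 families.

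Beyond the fixed lists, some genes of these 9 families passed. Of 77 mitochondrial ribosomal protein genes, 39 rose and 0 fell (median 0.63, camera adjusted p = 3.77e-15; adjusted p = 0.134 with an estimated correlation), with MRPL4 at 1.19 and MRPL14 at 1.01. Of 25 core spliceosome genes of the SNRP and LSM families, 14 rose and 0 fell (median 0.56, camera adjusted p = 1.88e-06; adjusted p = 0.134 with an estimated correlation), among them LSM7 (1.13) and SNRPD2 (1.05). Of 454 ZNF genes, 100 fell and 16 rose (median -0.44, camera adjusted p = 2.97e-08; adjusted p = 0.139 with an estimated correlation), with ZNF841 at -1.54. With the length and GC offset the medians were 0.34, 0.40 and -0.12, and 4, 5 and 0 genes rose while 0, 0 and 1 fell. Without it, 38, 11 and 338 genes of these families did not pass. Of 24 mitochondrial import genes of the TIMM and TOMM families 11 rose and 0 fell (camera adjusted p = 4.05e-05; adjusted p = 0.164 with an estimated correlation). Of 33 kinesin genes 9 fell and KIF22 rose, with an offset median of -0.18 (camera adjusted p = 0.000895; adjusted p = 0.134 with an estimated correlation). Of 21 nuclear pore genes 7 fell and NUP62 rose (camera adjusted p = 0.00410; adjusted p = 0.354 with an estimated correlation). Of 14 integrin genes 2 fell, ITGB1 (-1.50) and ITGA1 (-1.77), at a camera adjusted p of 0.0208 (adjusted p = 0.154 with an estimated correlation). The EIF3 and vacuolar ATPase families did not pass as lists (camera adjusted p = 0.122 and 0.502); 4 of 13 EIF3 genes rose and EIF3A fell, and 3 of 20 vacuolar ATPase genes rose and 0 fell. Among lists matched on length, GC content and level, the nuclear pore and integrin medians lay at percentiles 42.3 and 40.6, so neither family stood apart from matched genes. The mitochondrial ribosomal, spliceosome and zinc finger medians lay at percentiles 100, 99.4 and 0, and the import and kinesin medians at 93.1 and 3.40. With the offset 0 kinesin and 0 nuclear pore genes passed, and only TIMM50 and ITGA1 did of the import and integrin genes (edgeR).

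Genes that passed with the length and GC offset, ordered by size under the rule for named genes, included some that were less prominent without it. SPA17 had a log2 fold change of 1.99 with the offset and 1.63 without, and the respiratory subunit gene NDUFA9 1.82 and 1.29. ATP5F1E had 1.59 and 1.10, the potassium channel gene KCNMA1 1.59 and 1.11, and the chromatin remodeller gene CHD4 1.38 and 1.16. The offset took lengths of 3.61 kb for SPA17 and ATP5F1E and 8.36 kb for NDUFA9. Whether these match the expressed transcripts was not tested, so the larger rises with the offset may be overcorrection. Among falls were the interleukin-18 antagonist gene IL18BP (-1.59 and -1.15), ERVK3-1 (-1.54 and -1.39) and the gap junction gene GJA1 (-1.20 and -1.57). Relative to the 200 genes nearest in length, GC content and level, HAVCR1 differed by -1.82 between the groups, without overlap. Transcribed unprocessed pseudogenes had 17 down and 2 up of 210 without the offset. Processed pseudogenes went the other way, with 37 up and 10 down of 315, as did lncRNA genes, with 59 up and 24 down of 1791. With the offset the medians of processed pseudogenes and lncRNA genes went from 0.36 and 0.24 to -0.013 and 0.040. The median of transcribed unprocessed pseudogenes went from -0.050 to -0.34.

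Short and GC-rich transcripts were higher in the libraries labelled overexpression. The tables argue against less transcription over long genomic spans as the whole cause. The partial Spearman rho with span, given length and GC content, was -0.11, against -0.41 for length and 0.50 for GC content. The bootstrap SE of the span value was 0.0087 over genes, which are not independent replicates, so it does not measure the spread between libraries. Bias between libraries in RNA integrity or preparation is consistent with the trend also seen within groups, where single libraries deviated from their group mean with length at a rho of up to 0.358 in size. After the offset 248 genes passed, so the trend as modelled did not account for all gene calls. The offset used a fixed length per gene, which may differ from that of the expressed transcript. The calls left therefore do not exclude such bias as the whole cause. An effect of NFE2L1 on these transcripts was not tested and stays open, because the trend separates the groups.

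ACSL4 lay at percentile 9 of the 200 genes nearest to it in length, GC content and level, whose median log2 fold change was -0.50. That is inside the range set beforehand for the trend as the cause, so the same trend may account for part or all of its fall. With the offset its log2 fold change went from -1.01 (SE 0.26) to -0.42 (SE 0.18), and the call ended because the change shrank. Relative to those 200 genes ACSL4 still differed by -0.54 between the groups without overlap. It stood at 0.27, 0.50 and 0.04 in controls and 0.01, -0.61 and -0.21 in the libraries labelled overexpression. Control 3 and library 1 labelled overexpression were close there, so this difference does not exclude the trend as the whole cause. The proteasome and ribosomal lists lay at percentile 100 of 10000 lists matched on the same properties. Their medians of 0.65 and 0.92 lay above matched medians of 0.25 and 0.58. Members were matched singly, so the matched lists lack the correlation between members, estimated at 0.29 and 0.43. Their spread may thus be too narrow, and the percentile does not exclude the trend as the whole cause. Relative to matched genes, the proteasome list stood at -0.15, -0.16 and -0.15 in controls and at 0.11, 0.28 and 0.09 in libraries 1, 2 and 3 labelled overexpression. Whether NFE2L1 raised it stays open as a hypothesis. The proteasome list was highest in library 2, which had the most NFE2L1, but library 1, without more NFE2L1, was close to library 3. Library 2 also had the strongest trend with length. Its shortest bin lay 1.02 above its longest on the log2 scale, against 0.28 and 0.40 in libraries 1 and 3. Matching may not remove that trend fully, so the trend and NFE2L1 cannot be told apart here.

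NFE2L1 in library 1 labelled overexpression was at the control level. A library of the control group under a wrong label is an unlikely source, since over 2569 of the genes called without library 1, those also tested with all 6 libraries, it deviated from the control mean by a median of 0.83 on the log2 scale towards libraries 2 and 3. Left-out controls deviated by at most 0.23 by a similar measure. It was taken against the other controls only, over the genes of smallest p, called or not. Neither value removes the length and GC trend. With the offset library 1 deviated by 1.20, over 52 genes called without it. An unmodified culture handled with the overexpression samples, or a loss of expression of the construct, was not tested and stays open.

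The 6 libraries make 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 2876 genes, 1135 past 2-fold and 248 with the length and GC offset, each in 1 of the 10 splits, and the highest of the other splits gave 0 in each case. For the lists, the real split called 8 and the highest of the others 11, with 6 of the 10 splits calling as many as the real one.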
